A study of Mus musculus with 10 samples.

How the data were processed

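BRD2 and BRD4 ChIP-seq was performed on mouse ESCs in 10 libraries, and the BRD2 peak list of V6.5 ESCs was used here. Per the labels' protocols, ESCs were grown with irradiated mouse embryonic fibroblasts as feeders, so a share of fibroblast chromatin in the sample is possible, and chromatin was fragmented by sonication. Reads were aligned with Bowtie 1.0.1 and peaks were called with MACS 1.4.2 on mm9, per the submitters' processing notes. The calling threshold, the control library, the handling of duplicate reads and of reads that map to several places, and any pooling of replicates are not given in the sources used here.

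The deposited file gives for each peak a chromosome, a start, an end, a name and a score. The score is the authors' value from the peak caller. It was read as -10 times the log10 of the peak p-value, as in the BED output of MACS 1.4; this scale was inferred, since the file has no header. It depends on read depth and on the control, so it was used only to rank, filter and compare peaks within the list. For the copy number of X, autosomal scores were also divided by 2. The lowest deposited score was 90.04, next to 90, which on that scale is a peak p-value of 1e-09. Positions are printed counted from 1. The number of reads behind each peak is unknown, and no interval for occupancy was computed.

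Gene numbers per chromosome were taken from the RefSeq gene table of GRCm38.p6. Its coordinates were not used, because the peaks are on mm9 and positions of the 2 builds cannot be mixed. The end of the last peak stood for chromosome length. For these reasons the planned results on transcription start sites, gene lists at promoters, distal peaks, GC and CpG content and sequence motifs were not run, and peaks are named by position. The rule for peaks named in the text was fixed before the data were examined: the 10 with the highest score (ties by width, then position), the 5 widest and the 5 windows of 1 Mb with the most peaks.

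Correlations across the 19 autosomes were computed as Pearson's r and Spearman's rho with two-sided permutation tests (100000 permutations; the smallest p they can give is 1e-05) and Benjamini-Hochberg adjustment over the 4 relations. Clustering was the share of peaks on chromosomes 1 to 19 and X with another peak within 10 kb between edges. It was compared with 1000 placements of the same widths, drawn uniformly between the first and last peak of each chromosome. The placements ignored assembly gaps and mappability, and placed peaks could overlap, which raises the random share. Intervals of medians are exact order-statistic intervals at 95%, and that of rho comes from 1000 bootstrap samples of peaks. All of them are over peaks and do not measure variation between cultures.

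Of the 17 gene lists fixed before the data were examined, the 8 with at least 50 members on the autosomes were compared with peaks per gene across chromosomes. That limit and this use were chosen after the data were seen. The lists hold developmental transcription factors, cytosolic and mitochondrial ribosomal proteins, nuclear oxidative phosphorylation genes, cell cycle and replication genes, replication-dependent histones, olfactory and vomeronasal receptors, and keratins with keratin-associated proteins. The lists of developmental transcription factors, cytosolic ribosomal proteins and cell cycle genes were given by name, and all their members matched a symbol or synonym of the gene table. The others were drawn from symbols of that table by prefix, so their match was fixed by construction.

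The alternatives were the upper 50% or 25% of peaks by score, merging of peaks up to 1 kb apart, other chromosomes, other gene sets, bases covered in place of peak number, neighbour distances of 1, 5 and 50 kb, and other spans for the random placement. The clustering and correlation code was tested on simulated data. Of 20 random placements of the 11430 peaks, 0 passed the threshold of 0.05, and with 1000 peaks moved next to another the share with a neighbour went from 10.4% to 25.6% (permutation p = 0.0099, the smallest its 100 placements can give). Of 1000 pairs of unrelated columns over 19 rows, 50 passed the threshold. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.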

Results

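The series profiled 2 BET proteins, BRD2 and BRD4, by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse embryonic stem cells (ESCs). BET proteins carry tandem bromodomains that bind acetylated lysines on histones. The 10 libraries fall into 5 groups of 2. BRD2 was profiled in unmodified V6.5 cells, a male line from a cross of 129SvJae and C57BL/6 mice. BRD2 and BRD4 were each profiled in 2 transgenic lines that express YFP-tagged H2A.Z in place of the endogenous protein, which was depleted by a hairpin. H2A.Z is a histone variant found around promoters. One line carried wild type H2A.Z and the other K3R3, in which C-terminal lysines that accept ubiquitin were replaced by arginine. The comparison of those lines asked how H2A.Z ubiquitylation relates to BET protein binding.

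One peak list, of BRD2 in V6.5 ESCs, was analysed here. No binding value of the H2A.Z or K3R3 lines, and none of BRD4, entered the results, so the comparison of mutant with wild type H2A.Z was not made. The list belongs to replicate 1 of the V6.5 group. Whether it was called on that library alone or on both replicates pooled is not given in the sources used here. There is therefore no replicate error for any value below. Intervals and tests describe positions within this list and not the spread between cultures. Read depth is unknown, since the list holds no read counts. Peaks are given by position in mm9 and were not assigned to genes, because gene positions of that build were not used here.

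BRD2 occupied 11536 peaks, which together covered 20.7 Mb. The median peak width was 1595 bp (95% interval of the median over peaks 1583 to 1607 bp), with quartiles at 1270 and 2032 bp and a range of 415 to 13087 bp. The peak score was read as -10 times the log10 of the peak p-value, from the output format of the peak caller, since the file has no header. It had a median of 275.3 (95% interval 268.4 to 282.2) and quartiles of 147.9 and 570.3. The lowest score was 90.04, just above 90, which on that scale is a peak p-value of 1e-09. At the upper end 52 peaks were tied at a score of exactly 3100 and 9 peaks lay above it. The score does not order the 52 tied peaks. A tie at a round value may be a limit of the scale. Whether the 9 peaks above it are stronger or weaker than the tied peaks is therefore not settled. These 61 peaks (0.529% of the list) were also broad, with a median width of 4817 bp and a range of 2499 to 13087 bp.

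Peaks are named here in the order of the deposited score, which may not rank peaks at or above 3100 by strength. The highest score was 3233.06 to the 2 decimals of the file. It was shared by a 5022 bp peak on chromosome 10 (67597992 to 67603013) and a 3833 bp peak on chromosome 7 (16984188 to 16988020). A 3565 bp peak on chromosome 1 (180247534 to 180251098) scored 3214, and a 5547 bp peak near the start of chromosome 7 (3217121 to 3222667) scored 3207. Chromosome 6 held 2 of the highest 10 peaks, at 117855938 to 117859062 (score 3130) and at 122710669 to 122718204 (score 3128). Chromosome 3 held 3 of them, at 88137816 to 88141806 (score 3123), at 107134877 to 107137823 (score 3121) and at 88373392 to 88384668 (score 3104). The tenth, on chromosome 9 (58116058 to 58129144), was at 3100 and led the tied peaks by its width of 13087 bp, which also made it the widest peak of the list. The other 4 of the 5 widest peaks lay on chromosome 11 (79944379 to 79956345, 11967 bp), chromosome 9 (78215415 to 78226879, 11465 bp), chromosome 19 (5796788 to 5808076, 11289 bp) and chromosome 3 (the 11277 bp peak with score 3104). Width alone did not mark the highest scores, since the chromosome 11 peak scored only 543.3 and the second chromosome 9 peak 1230.

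Wider peaks had higher scores across the list. Spearman's rho between score and width was 0.696 over the 11536 peaks (95% bootstrap interval 0.685 to 0.706), a relation across peaks, which are not independent replicates. The median score was 128 in the narrowest quartile of peaks and 226.9, 388 and 674.8 in the following quartiles. Within the upper 50% of peaks by score, rho was 0.473. Width and score both come from the same call of each peak, so the relation may in part be set by the peak caller.

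**Figure D1:**
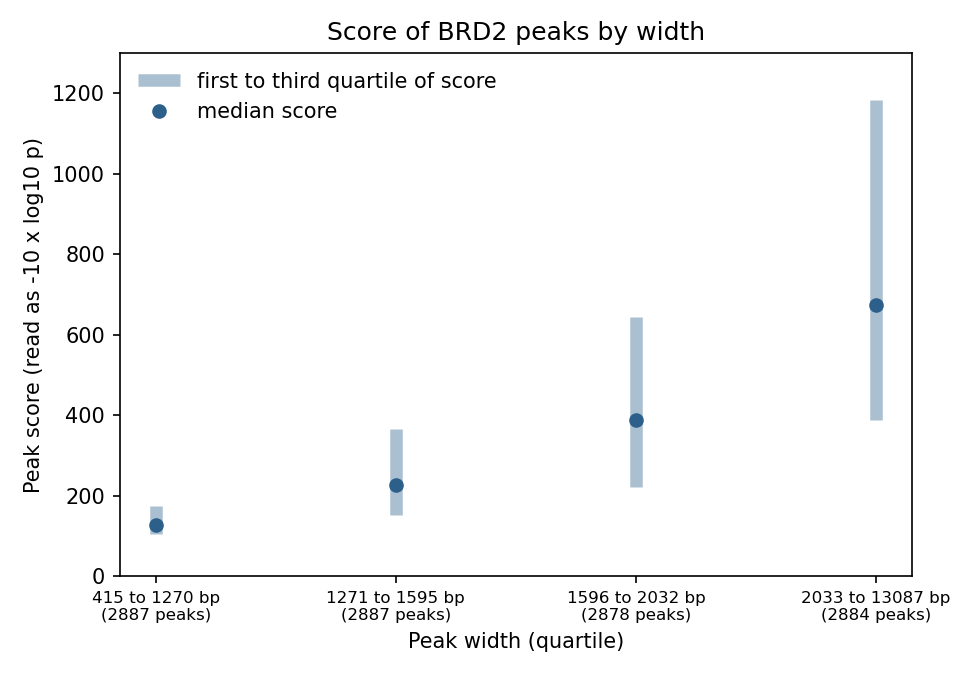
Peak score (vertical axis, read as -10 x log10 p, from 0) for the 4 quartiles of peak width (horizontal axis, with the width range in bp and the number of peaks). Points are medians and bars run from the first to the third quartile; the median rose from 128 in the narrowest to 674.8 in the widest quartile.

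BRD2 peaks followed the gene content of the chromosomes. Chromosomes 2 and 11, which are rich in genes, carried 894 and 863 peaks, and chromosome 18, the autosome with the fewest protein-coding genes, carried 331. Across the 19 autosomes the number of peaks correlated with the number of protein-coding genes (Pearson's r = 0.878, permutation p = 2e-05; Spearman's rho = 0.907, permutation p = 2e-05). The correlation with chromosome length, taken as the end of the last peak, was lower (r = 0.715, permutation p = 0.00049; rho = 0.751, permutation p = 0.00035). All 4 permutation tests passed Benjamini-Hochberg adjustment (adjusted p = 4e-05 for both coefficients with genes, 0.00049 and 0.00047 for those with length). Whether the relation with genes exceeds that with length was not tested. Without chromosomes 7 and 2, the farthest from the median gene number, r with genes was 0.926, and without chromosomes 1 and 19 r with length was 0.701. All tests were two-sided, with 100000 permutations, and chromosomes are not replicates.

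Relative to gene number, chromosome 8 was the richest autosome and chromosome 7 the poorest. The autosomes had 55.4 ± 7.63 peaks per 100 protein-coding genes (SD over 19 autosomes), with 72.8 on chromosome 8 and 36.8 on chromosome 7. Chromosome 7 carried 417 olfactory and vomeronasal receptor genes, which are expressed chiefly in sensory neurons, and these made up 20.5% of its protein-coding genes. Chromosome 8 carried 5 such genes, or 0.479%. Without the receptor genes chromosome 7 was still the lowest autosome, with 46.3 peaks per 100 other protein-coding genes, and chromosome 8 the highest with 73.1. Per Mb, the autosomes had 4.56 ± 0.973 peaks (SD over 19 autosomes), from 3.46 on chromosome 12 to 7.09 on chromosome 11.

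The X chromosome had fewer peaks than its genes or length would give at the autosomal rate. It carried 289 peaks, or 29.9 per 100 protein-coding genes (exact 95% Poisson interval 26.6 to 33.6, counting error only), below every one of the 19 autosomes and 0.540 times their mean. Per Mb it had 1.74 peaks, 0.381 times the autosomal mean. The peaks called on X did not score detectably lower than autosomal peaks: the median score was 254.8 (95% interval 209.3 to 279.6) against 275.9 (268.5 to 283.8), a difference of -21.1 (two-sided permutation p = 0.36, 10000 permutations). They were narrower, with a median width of 1408 bp (95% interval 1324 to 1471 bp) against 1602 bp (1589 to 1614 bp). This difference of -194 bp had a two-sided permutation p of 0.0001, the smallest that 10000 permutations can give. The test treats peaks as independent, and widths on single autosomes were not compared here. It therefore does not show that X falls outside their spread. The median score of X lay within the range of the autosomal medians (252.7 to 298.3). The Y chromosome carried 2 peaks, with scores of 91.96 and 111.4. A male line holds 1 copy of X and of Y.

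**Figure D2:**
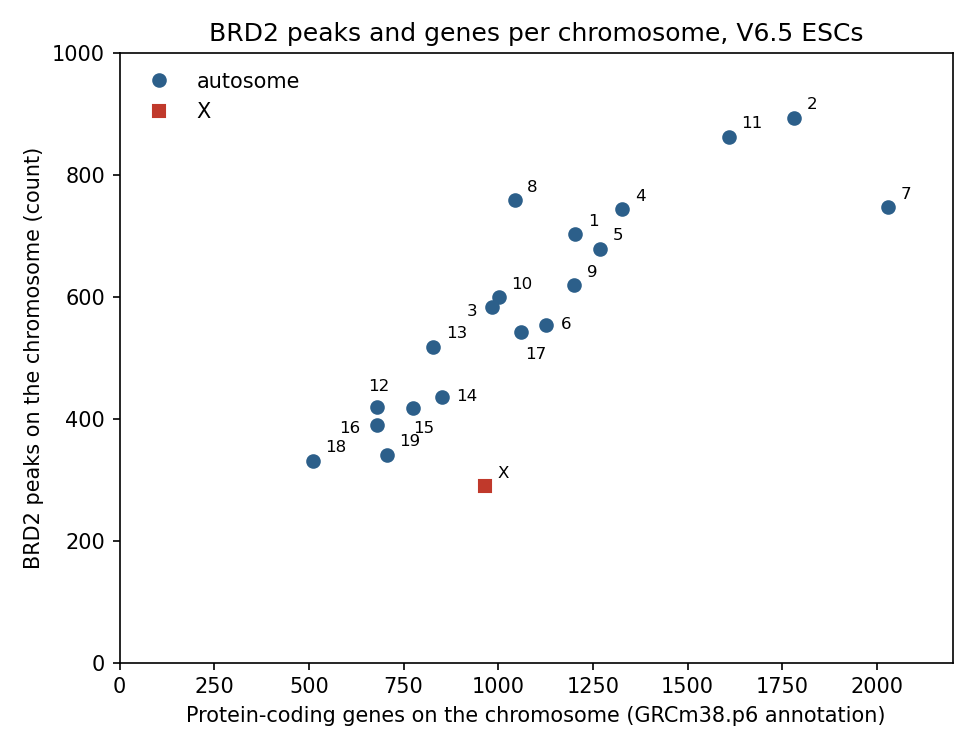
Number of BRD2 peaks (vertical axis) against the number of protein-coding genes in the GRCm38.p6 annotation (horizontal axis), 1 point per chromosome, circles for autosomes and a square for X. The autosomes rise together from chromosome 18 (331 peaks) to chromosome 2 (894 peaks), chromosome 7 lies below that trend with 747 peaks, and X lies lowest with 289.

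BRD2 peaks were grouped along the chromosomes. On chromosomes 1 to 19 and X, 2977 of 11430 peaks (26.0%) had another peak within 10 kb, against 10.6% ± 0.373 (SD) in 1000 random placements of the same peak widths within each chromosome. The highest of those placements gave 11.8%, so the permutation p was 0.001, the smallest that 1000 placements can give (one-sided). The excess was 2.46-fold at 10 kb and 1.73-fold at 50 kb, where 66.4% of peaks had a neighbour. When each peak was instead placed at random within its own 1 Mb window, an alternative chosen after the data were seen, the excess was 1.42-fold (mean of the placements 18.3%).

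**Figure D3:**
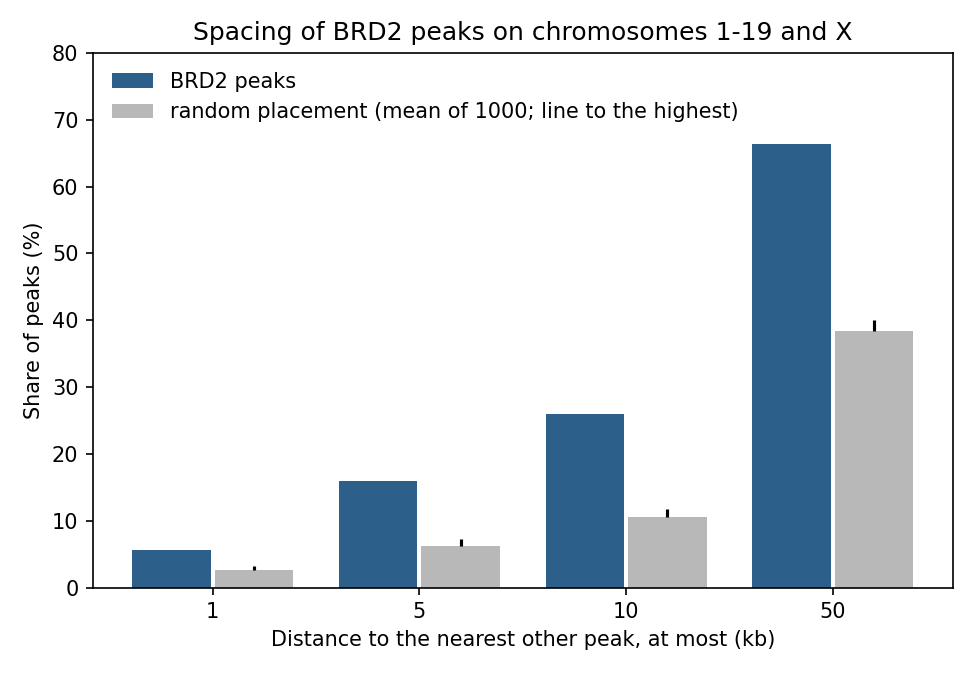
Share of peaks on chromosomes 1 to 19 and X (vertical axis, %, from 0) whose nearest other peak lies within 1, 5, 10 or 50 kb (horizontal axis). Blue bars are BRD2 peaks, grey bars the mean of 1000 random placements with a line up to the highest of them; at each distance the peaks exceed the highest placement, as at 10 kb with 26.0% against 11.8%.

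The median gap between neighbouring peaks was 60.9 kb (quartiles 20.7 and 181.7 kb). Of the 2578 windows of 1 Mb between the first and the last peak of each chromosome, 604 (23.4%) held no peak, against 63.5 on average and at most 86 in the random placements. Peaks less than 10 kb apart formed 1307 runs of 2 or more peaks, 23 of them with 5 or more. Peaks in runs had a median score of 266.7 and single peaks 279.3, a difference within the permutation range (p = 0.14, two-sided, 10000 permutations).

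Of the 5 windows of 1 Mb with the most peaks, 1 lay on sequence that mm9 does not place on a chromosome and is given with such sequences in the closing section. The other 4 were on chromosome 8 (87000001 to 88000000, 34 peaks with a median score of 523.2), chromosome 7 (134000001 to 135000000, 30 peaks, median score 389.8) and chromosome 10 (80000001 to 81000000 and 127000001 to 128000000, 29 peaks each, median scores 209.4 and 242.9). The random placements put at most 20 peaks in a window.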

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

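The tests in this part on X and on unplaced sequences were chosen after the results were seen; the 2 tests on the spacing of peaks were written down before their results were seen, although placement inside 1 Mb windows was added after the data were examined. The gene number and copy number of X, properties of the cells, were tested for the shortfall on X. No group of the design was tested as an explanation, since 1 peak list was used.

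Sequences that mm9 does not place on a chromosome carried 104 peaks (0.901% of the list), a signal that the comparisons of chromosomes and of spacing do not use, although the counts, widths and scores of the whole list include it. Whether they exceed the background was not tested, since no control peak list was used. Of these, 85 lay on the unplaced collection Un_random, between 3.398 and 5.9 Mb. It had 14.4 peaks per Mb up to its last peak, against at most 7.09 averaged over a whole autosome. Such averages are not a like measure for a short sequence, since single 1 Mb windows of placed chromosomes held up to 34 peaks. The Un_random window from 5000001 to 6000000 held 41 peaks, the most of any window in the list. Since Un_random is a collection of unplaced sequences, neither this window nor the rate per Mb need describe 1 continuous region. With peaks up to 1 kb apart merged, 56 peaks or 9.49 per Mb remained on Un_random, still above the highest autosome (6.91 after the same merging). This argues against splits at gaps up to 1 kb as the whole explanation of a rate above those autosomal averages. Splits at wider gaps were not tested. Reads from several genomic copies placed on 1 assembled copy may raise the number of called peaks there, but the median score of unplaced peaks differed by only 22.96 from that of placed peaks (permutation p = 0.53), which does not decide it, since the score was not corrected for copy number.

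The shortfall of peaks on X was not matched by its gene number. With 29.92 peaks per 100 protein-coding genes, and an upper counting limit of 33.6, X stayed below the lowest autosome at 36.8, which argues against fewer genes as the whole cause. A single X copy in a male line could lower the score of every X peak and push weak ones under the threshold. Division by 2 stands here for that loss. This is an assumption that was not tested, since the score also depends on read depth and on the control. If autosomal scores are divided by 2 and peaks under the lowest score removed, 66.8% of autosomal peaks remain, which gives 24.9 to 47.3 per 100 genes, a range that holds X, but at least 2.32 per Mb, above the 1.74 of X. The remaining divided scores have a median of 220.6, and the interval of the X median (209.3 to 279.6) holds both this value and the undivided autosomal median of 275.9, so the part played by copy number cannot be told apart from other differences of X. Peaks on X were also narrower than autosomal peaks (median 1408 against 1602 bp). The width that a single copy would give was not modelled, and neither assembly gaps nor mappability of X were tested.

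For the excess of close neighbours 2 explanations were tested, the first of them technical. Uneven mappability and assembly gaps, which the placements ignored, were not tested directly. With peaks up to 1 kb apart merged, 21.92% of 11100 peaks still had a neighbour within 10 kb. The highest of 1000 placements gave 11.5%, which argues against splits at gaps up to 1 kb as the whole explanation. Regions split at gaps of 1 to 10 kb would still count as neighbours, so such splitting stays open. Uneven density at the 1 Mb scale, such as gene-rich regions, gave at most 19.55% when each peak was placed at random in its own window, against 26.0% observed. Density below that scale, including neighbouring or bidirectional promoters and enhancers of 1 gene, stays open, because peaks were not assigned to genes here.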

How the results depend on the processing

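No paired analysis was possible because 1 peak list was used, with no values per replicate; for the same reason no replicate could be left out. The correlation of peaks with protein-coding genes kept its direction and passed the threshold under all 8 alternatives (r 0.817 to 0.932, rho 0.876 to 0.939), with the upper ends from gene numbers without receptor genes, added after the data were seen. So did the correlation with length under all 6 (r 0.552 to 0.729, rho 0.550 to 0.777; the lowest of both with X included). The excess of neighbours passed under all 8 alternatives, from 1.42-fold (each peak placed in its own 1 Mb window, added after the data were seen) to 2.66-fold (upper 25% of peaks by score). The number of peaks was by construction 5768 in the upper 50% and 2884 in the upper 25% by score, and 11175 after merging. Rho between score and width was 0.473 in the upper 50% of peaks, which spans fewer scores by construction, and 0.688 without the widest 1% of peaks. Alternatives on distance to a transcription start site, promoter type, sequence content and motif width were not run, since they need gene positions or sequence of mm9. Read depth is unknown, the 52 peaks tied at a score of 3100 are not ordered by score, and the calling threshold hides weaker sites.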

Other observations

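Among the runs of BRD2 peaks less than 10 kb apart, 4 held 6 or more peaks and 19 held exactly 5. The 4 runs with the most peaks and the run of 5 with the most bases covered by peaks are given here, a choice made after the data were seen; the other runs of 5 are not listed. A run of 10 peaks spanned 57.3 kb of chromosome 13 (23621943 to 23679206), with a median score of 393.5. A second run lay close by on the same chromosome (23830212 to 23856814), with 6 peaks and a median score of 805.4. Chromosome 7 held a run of 8 peaks over 66.5 kb (134338476 to 134404994, median score 371.7) and a run of 5 peaks over 30.9 kb (3191721 to 3222667). The latter had a median score of 3100, the value at which 52 peaks are tied, and contained the chromosome 7 peak with score 3207. A run of 6 peaks on chromosome 8 (86707047 to 86728459) had a median score of 253.2. At the other extreme, 3 of the 5 longest stretches without a peak were on X, of 14.2 Mb (112090044 to 126280393), 10.6 Mb (23532445 to 34137739) and 8.27 Mb (57658121 to 65930921). The others were on chromosome 6 (72909191 to 81873137, 8.96 Mb) and chromosome 8 (98677475 to 106771817, 8.09 Mb). Whether assembly gaps, low mappability or the low number of peaks on X account for these stretches was not tested.

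The share of olfactory and vomeronasal receptor genes among a chromosome's genes went with its peaks per gene, and passed adjustment over the 8 lists tested. The hypothesis, written before its test, was that chromosomes rich in these genes carry fewer peaks per gene. Both measures are divided by the same gene number, which includes the receptor genes. Where peaks do not follow receptor genes, this arithmetic alone lowers peaks per gene, and the permutation test does not allow for it. Across the 19 autosomes, Spearman's rho was -0.709 (permutation p = 0.0011, adjusted p = 0.0086 over the 8 lists) and Pearson's r was -0.751 (permutation p = 0.00019, adjusted p = 0.0015). Without chromosomes 7 and 2, which hold the largest shares, rho was -0.610 and r was -0.594, each with a permutation p of 0.011. Each other list was likewise taken without its own 2 chromosomes farthest from the median share, and 7 lists still varied. Over these 7 the adjusted p of the permutation tests for receptor genes was 0.077, although the lists left out different chromosomes. The call after adjustment therefore leans on chromosomes 7 and 2. In a least-squares fit chosen after this result, other protein-coding genes carried 60.8 ± 2.46 peaks per 100 genes (jackknife SE over 19 autosomes) and receptor genes -39.69 ± 36.35. A negative number of peaks has no meaning of its own, and the receptor term was -6.60 without chromosome 7, so it only says that these genes may add fewer peaks than others. Receptor genes sit in large clusters, and what else those regions lack was not tested. Per 100 other protein-coding genes, chromosome 2 carried 59.8 peaks, near the autosomal mean of 58.6, and chromosome 7 carried 46.3. Whether the share of receptor genes goes with that rate was not tested.

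The other 7 lists did not pass adjustment over the 8 lists, which does not show that they are unrelated to peaks per gene, and differences between lists were not tested. Rho was 0.328 for developmental transcription factors (adjusted p = 0.34), 0.349 for replication-dependent histones (adjusted p = 0.34) and -0.419 for mitochondrial ribosomal proteins (adjusted p = 0.30). The histone value rests on chromosomes 13 and 3, since the share of that list did not vary among the other autosomes. Rho was -0.056 for cytosolic ribosomal proteins, -0.128 for oxidative phosphorylation genes, 0.026 for cell cycle and replication genes and 0.017 for keratins, each with an adjusted p of 0.95. The permutation test over 19 chromosomes cannot show that a list is free of peaks or rich in them, since no peak was assigned to a gene.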
